A study of Mus musculus with 12 samples.

How the data were processed

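The values were read from the scanner output of 12 one-colour Agilent arrays, extracted with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Per the file headers the deposited processed signal is a background-subtracted intensity on a linear scale, and it was log2-transformed here. The deposited series matrix holds log2 values per the labels, in which all columns share 1 distribution (median 3.84 for each array), and correlates with the scanner log2 signal at r of 0.998 or more. How these matrix values were made is not given in the sources used here, and they served as an alternative only. Quantile normalization gives columns of 1 distribution too, and both settings called similar numbers of genes for E2f1 knockout (3772 and 3816). They are therefore not separate checks. Per the labels 50 ng of RNA was labelled per liver. Groups were taken from the sample titles and characteristics. The source field of the E2f1 knockout samples, which names vehicle and chow, contradicts the other fields and was not used to group samples. The genotype names in the figures are those of the labels.

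Control spots and outlier spots were left out, and spots of the same probe were averaged. The 59305 remaining spots gave 55681 probes, of which 55249 had 1 spot, 399 had 10 and 33 had 2. The main value was the log2 processed signal minus the array's 75th percentile, so values are relative within an array. A probe was tested if it was well above background on at least 3 of 4 arrays of any group, which left 28442 probes. Gene names came through RefSeq accessions for 28026 probes, through a current symbol in the file for 3418 and through a synonym for 295, and 23942 kept the name in the file. There were 34607 distinct names on the array. The brightest tested probe stood for each gene, giving 20576 genes, 99 of them with a missing value on some array. Of 50 named genes with several tested probes, the sign differed between probes for 6 in E2f1 knockout and 4 in E2f2-labelled livers. Genes where this occurred included Ahcy, Amy2a5, Enpp1, Ifi202b, Mcm3, Rbbp9 and Sparc. Positions are those of the files (mm9), and a later assembly's list of genes gave names only.

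Genes were tested with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), in a single fit of all 12 arrays without covariates, with 9 residual degrees of freedom and a prior of 3.13. Benjamini-Hochberg adjusted p under 0.05 was called. Because each slide held 1 array of each group, fold changes of genes with a value on every array were the same with and without the slide as a block (6 residual degrees of freedom). Of 12 pairs of arrays on a slide, 10 had deviations from their group means that correlated above 0.1, with r from 0.04 to 0.42 across genes, and 11 of 12 arrays correlated best with arrays of their own number. The unblocked fit stayed the main one, as fixed before the data were examined, and blocked counts are given beside it.

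Gene lists were written from general knowledge, with 41 lists, 1064 entries and 1017 distinct genes, 44 of them on more than 1 list and 913 tested. They covered E2F targets in DNA replication, mitosis and G2/M, the E2F and RB family, p53 targets, mitochondrial fatty acid oxidation, PPARA targets and peroxisomal oxidation, lipogenesis and triglyceride synthesis, lipid droplets and steatosis, cholesterol synthesis, lipoproteins and cholesterol transport, bile acid synthesis and transport, xenobiotic metabolism, NRF2 targets and glucose metabolism. Further lists held liver tumour and oncofetal markers, pericentral and Wnt targets, periportal genes and the urea cycle, the methionine cycle and phosphatidylcholine, oxidative phosphorylation, the unfolded protein and integrated stress response, inflammatory cytokines and receptors, the acute phase response, interferon-stimulated genes and fibrosis and stellate cell markers. The rest held markers of macrophages and Kupffer cells, T and NK cells, B and plasma cells, neutrophils, cholangiocytes, endothelial cells, hepatocytes, adipocytes, exocrine pancreas, erythroid cells and skeletal muscle, the circadian clock, immediate early genes, male-biased and female-biased liver genes, sex chromosome genes and housekeeping genes. Lists were tested with camera in limma with a preset inter-gene correlation of 0.01, again with a correlation estimated per list, and with fry.

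Named genes followed a rule fixed before the values were read. It took E2f1, E2f2 and Cpt2, the 8 largest rises and 8 largest falls among called genes with non-overlapping groups, up to 4 members per list, and 8 genes called in both comparisons with wild type. Examples in the text were drawn from these. Changes of genes with 0 of 4 arrays above background in a group are given as lower bounds.

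Alternatives were normexp background correction (offset 50), quantile normalization, median centring, series matrix values, no filter on dim probes, a filter on all 12 arrays, outlier spots kept, the mean of all probes, the slide as a block, fits of 2 groups, an intensity trend with robust variances, array weights, each array left out, and separate wild type arrays for each knockout. In a self-test on data with 200 genes changed artificially, 59%, 43% and 43% of changes of log2 1 and 89%, 84% and 78% of log2 2 were recovered in the E2f1 knockout, E2f2-labelled and direct comparisons. False calls were 6.3%, 5.2% and 4% of calls. A shifted list was recovered in each (camera adjusted p 2.9e-40, 4e-31 and 2.3e-32), with 0 lists called without a change. Genes were drawn independently in this self-test, so it does not check list calls where the genes of a list are correlated. Raw images and tissue histology were not used here. Results of some single genes are not reported.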

Results

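RNA from the livers of 12 mice was measured on Agilent one-colour arrays, with 1 array per mouse. The labels give 3 groups of 4 separate mice: wild type (129/Sv x C57BL/6), E2f1 knockout and E2f2 knockout. E2f1 and E2f2 encode transcription factors that bind the promoters of cell cycle genes. Per the treatment protocol, mice received the liver carcinogen diethylnitrosamine at 25 mg/kg on postnatal day 14. They then ate a high-fat diet with 60% of calories from fat for 32 weeks and were killed at 9 months of age after a fast of 4 hours. One label field of the E2f1 knockout mice names vehicle and chow instead, while their titles, descriptions and characteristics and the protocol name diethylnitrosamine and high-fat diet. The labels do not settle this conflict, so each comparison with the E2f1 knockout mice carries it. The sex of the mice, the hour of killing and the part of each gene that was deleted are not given in the sources used here.

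The 75th percentile of the signal lay between 119.2 and 238.3 intensity units per array, and between 44.8% and 54.5% of the probes were well above background. The number of arrays limits the precision of every value. Across genes, Pearson's r lay between 0.954 and 0.988 for the 18 pairs of arrays within a group and between 0.928 and 0.980 for the 48 pairs between groups. Genes are not independent replicates in these correlations. The first principal component held 44.3% of the variance, with wild type arrays between -95.8 and -33.1 and the other arrays between 14.0 and 51.0. On the second, with 12.3%, the E2f1 knockout arrays lay between -45.0 and -24.9 and the arrays labelled E2f2 knockout between 20.5 and 41.4. Fold changes below are on the log2 scale and are followed by their standard error (SE), with n = 4 livers per group. Adjusted p values of genes come from limma and those of gene lists from camera.

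The targeted genes were examined first, as a check of the labels. The E2f1 probe (chromosome 2, mm9 positions 154385798 to 154385857) averaged 0.06 ± 0.31 (SD, n = 4) in wild type and -0.77 ± 0.11 in E2f1 knockout livers, relative to the 75th percentile of the array. The difference was -0.82 ± 0.19 (SE; adjusted p = 0.0114), and the probe stayed well above background on all 4 knockout arrays. The E2f2 probe (chromosome 4, mm9 positions 135750562 to 135750621) averaged 0.80 ± 0.26 in wild type and 0.54 ± 0.25 in livers labelled E2f2 knockout, a difference of -0.26 ± 0.21 that did not pass (adjusted p = 0.408). In E2f1 knockout livers E2f2 averaged -0.70 ± 0.38, a difference from wild type of -1.50 ± 0.21 (adjusted p = 0.00141). E2f1 in the livers labelled E2f2 knockout differed from wild type by -0.16 ± 0.19 (adjusted p = 0.58). A probe outside the deleted part checks nothing, and whether either probe lies inside it is not known here. The E2f2 group is therefore called the E2f2-labelled livers.

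The study is known to focus on Cpt2, which encodes carnitine palmitoyltransferase 2 of the mitochondrial fatty acid import machinery. Its brighter probe (chromosome 4, mm9 positions 107576591 to 107576650) averaged 4.43 ± 0.51 (SD) in wild type, 5.77 ± 0.21 in E2f1 knockout and 5.79 ± 0.28 in E2f2-labelled livers. Cpt2 rose by 1.34 ± 0.24 (SE; adjusted p = 0.004) and by 1.36 ± 0.24 (adjusted p = 0.00341), higher in 4 of 4 arrays of each group than in any wild type array. The second Cpt2 probe rose by 1.60 ± 0.26 and 0.98 ± 0.26.

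**Figure D1:**
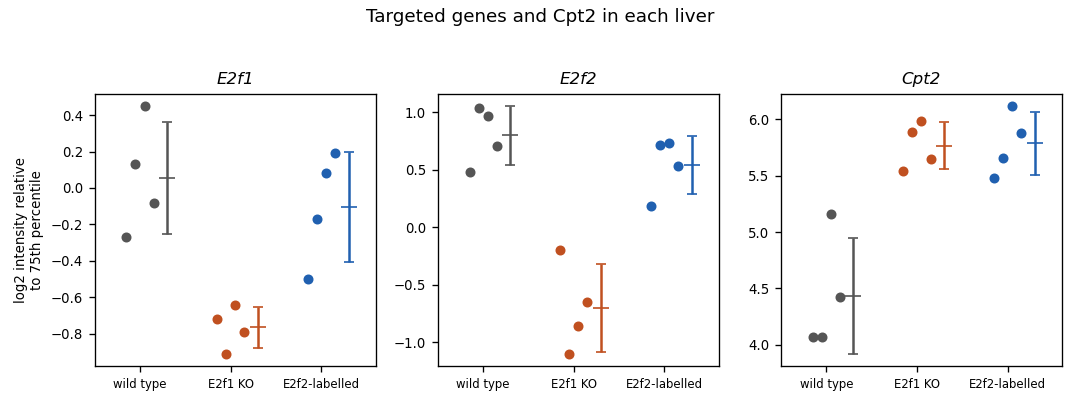
Points are single livers, and horizontal bars with whiskers are the mean and SD (n = 4) of E2f1, E2f2 and Cpt2 as log2 intensity relative to the array's 75th percentile. E2f2 averaged 0.80 in wild type, -0.70 in E2f1 knockout and 0.54 in E2f2-labelled livers, and Cpt2 was higher in the 4 E2f1 knockout and 4 E2f2-labelled livers than in the 4 wild type livers.

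The comparison of E2f1 knockout with wild type asks what loss of E2F1 changes in livers exposed to a carcinogen and dietary fat. With a preset correlation camera called 28 of 41 lists, and with an estimated correlation 0 (smallest adjusted p = 0.18), so the list shifts below depend on that setting. By that preset test, genes of cell division, liver tumours and inflammation were lower in livers labelled E2f1 knockout. Genes of fatty acid oxidation, respiration and mature hepatocyte metabolism were higher. Male-biased liver genes and genes of the circadian clock also rose, and female-biased genes fell.

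Of 20576 genes tested, limma called 4234, with 2709 higher and 1525 lower (64.0% higher) in E2f1 knockout livers, and 2049 of these differed at least 2-fold (1054 higher, 995 lower). The median of all genes lay at 0.13. With quantile normalization it lay at 0.03 and 50.4% of 3816 called genes were higher, so the excess of rises depended on the scaling. In 4364 genes the values of the groups did not overlap, against 2.86% of genes by chance. The count fell to 2511 without wild type replicate 2 and to 2646 without E2f1 knockout replicate 3. Each slide held 1 array of each group, and with the slide as a block 5487 genes passed, 4116 of them in both fits. The array position on the slide was the same for every mouse of a group, so position and group cannot be told apart.

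Among genes of mitosis, 25 of the 31 tested fell and 0 rose, with the same numbers adjusted over the list alone. Their median was -1.70, and within the 4 slides it ranged from -2.12 to -0.44 (camera adjusted p = 3.2e-17, adjusted p = 0.25 with an estimated correlation). Over 26 alternatives the median ranged from -1.929 to -0.646, the smallest with normexp. Mki67, the proliferation antigen Ki-67, fell by 2.34 ± 0.54 (adjusted p = 0.0112). Prc1, which bundles microtubules of the spindle, fell by 2.56 ± 0.48 and was well above background on 3 of the 4 E2f1 knockout arrays. E2F targets of DNA replication moved less, with 2 of 41 higher and 5 lower (2 and 5 adjusted over the list alone) and a median of -0.16 (adjusted p = 0.0076, adjusted p = 0.3 with an estimated correlation, 0.16 by fry; median -0.263 to -0.067 over alternatives). The origin factor Mcm10 rose by 2.52 ± 0.54, while Uhrf1, which maintains DNA methylation, fell by 1.39 ± 0.28. In the E2F and RB family 8 of 24 genes fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.53 (adjusted p = 4.3e-05, adjusted p = 0.18 with an estimated correlation). The targeted gene E2f1 itself and E2f2 are members of this list and were among the 8 that fell. The kinase inhibitors Cdkn2a and Cdkn2b fell by 3.08 ± 0.48 and 4.84 ± 1.04, the latter well above background on 3 of 4 E2f1 knockout arrays. Of 25 targets of p53, 11 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.81 (adjusted p = 2.2e-08, adjusted p = 0.25 with an estimated correlation). That median ranged from -1.4 to -0.04 within slides and from -0.905 to -0.434 over alternatives. Phlda3, a p53-induced repressor of AKT, fell by 3.25 ± 0.38.

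Liver tumour and oncofetal markers fell in 22 of 32 cases and rose in 0 (24 and 1 adjusted over the list alone). Their median was -2.29, between -2.85 and -1.53 within slides (adjusted p = 3.4e-15, adjusted p = 0.2 with an estimated correlation). Akr1c18 and Ly6d fell by 4.99 ± 0.66 (adjusted p = 0.00105) and 4.92 ± 0.79 (adjusted p = 0.0024). The oncofetal proteoglycan Gpc3 fell by 3.61 ± 1.15 (adjusted p = 0.0437), with 1 of 4 wild type livers as low as the knockouts.

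Mitochondrial fatty acid oxidation genes rose in 21 of 26 cases and fell in 0 (24 and 0 adjusted over the list alone), with a median of 0.79 and 0.52 to 1.14 within slides (adjusted p = 5.1e-10, adjusted p = 0.28 with an estimated correlation). Acsl1 and Eci2, enzymes of acyl-CoA synthesis and oxidation, rose by 1.49 ± 0.33 and 1.31 ± 0.22. PPARA targets rose in 16 of 30 cases (23 adjusted over the list alone), with a median of 1.15 (adjusted p = 1.6e-05, adjusted p = 0.35 with an estimated correlation). Angptl4, which encodes an inhibitor of lipoprotein lipase, rose by 1.65 ± 0.35, while 1 target, the hormone gene Fgf21, fell by 1.38 ± 0.33. In oxidative phosphorylation 32 of 35 genes rose and 0 fell (34 and 0 adjusted over the list alone), with a median of 0.73 and 0.66 to 0.82 within slides (adjusted p = 3.2e-13, adjusted p = 0.28 with an estimated correlation). Sdhb and Ndufv1 rose by 1.05 ± 0.20 and 0.93 ± 0.19.

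Lipogenic genes went both ways, with 6 of 26 higher and 3 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.86). The desaturase gene Scd2 fell by 3.83 ± 0.43 and the phosphatidate phosphatase gene Lpin1 rose by 2.24 ± 0.47. Of 25 genes of lipid droplets, 5 rose and 6 fell, with a median of -0.22 (adjusted p = 0.041, adjusted p = 0.32 with an estimated correlation). That call held in 14 of 26 alternatives (range of adjusted p 0.004 to 0.32). It was lost without wild type replicate 3 (0.061), E2f1 knockout replicate 3 (0.056) or E2f1 knockout replicate 4 (0.1), with the slide as a block (0.075) and by fry (0.11). Without E2f1 knockout replicate 4 the median turned to 0.059. E2f1 knockout replicate 1 stood apart from the other 3 in the median of this list (2.15 against 0.98 to 1.10) and of adipocyte markers (2.53 against -2.44 to -2.28). Without that array Fabp4, a member of both lists, passed at -2.677 (adjusted p = 0.0013; range 0.0013 to 0.27). Apoa4, which coats lipoproteins and fell by 4.60 ± 0.47, and Lpl, the lipoprotein lipase gene, which fell by 2.56 ± 0.38, were among those 6. Cholesterol synthesis (3 of 26 higher, 0 lower) and lipoproteins (5 of 25 higher, 3 lower) were not called (adjusted p = 0.95 for both).

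Metabolic genes of hepatocytes rose in several classes. The numbers were 14 of 22 for bile acids (1 fell), 17 of 33 for xenobiotic metabolism (3 fell), 16 of 26 for glucose metabolism, 14 of 22 for periportal genes and 15 of 24 for the methionine cycle (1 fell). Pericentral genes rose in 8 of 22 cases and hepatocyte markers in 11 of 28. Adjusted over the list alone the rises were 15, 18, 17, 15, 17, 12 and 13. The medians ran from 0.39 for hepatocyte markers to 1.13 for pericentral genes, whose values within slides spanned 0.07 to 2.06. Camera adjusted p lay between 2.3e-05 for glucose metabolism and 0.00067 for hepatocyte markers (adjusted p = 0.3 and adjusted p = 0.35 with an estimated correlation). With an estimated correlation the others were lost too, at 0.29 for bile acids, 0.36 for xenobiotic metabolism, 0.39 for pericentral genes, 0.29 for periportal genes and 0.32 for the methionine cycle. The call of the hepatocyte markers ended with quantile normalization, at a median of 0.14 (adjusted p = 0.12). Pck1, which encodes an enzyme of gluconeogenesis, rose by 2.33 ± 0.24 (adjusted p = 0.000186), the bile acid hydroxylase gene Cyp7b1 by 3.05 ± 0.45 (adjusted p = 0.00161) and the pericentral gene Cyp2e1 by 2.10 ± 0.46 (adjusted p = 0.00856). Not called were NRF2 targets (2 of 22 higher, 4 lower, adjusted p = 0.77), the unfolded protein response (7 of 29 higher, 5 lower, adjusted p = 0.82) and the acute phase response (2 of 30 higher, adjusted p = 0.95).

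Inflammatory cytokines and receptors fell in 11 of 28 cases and rose in 2 (13 and 2 adjusted over the list alone), with a median of -1.11 (adjusted p = 2.6e-07, adjusted p = 0.26 with an estimated correlation). Over the alternatives this median ranged from -1.139 to -0.481, the smallest with normexp. The chemokine gene Ccl4 fell by 3.11 ± 0.40 and the chemokine receptor gene Cx3cr1 by 2.67 ± 0.38. Interferon-stimulated genes fell in 11 of 32 cases and rose in 0 (19 and 0 adjusted over the list alone), with a median of -0.63 (adjusted p = 4.5e-12, adjusted p = 0.2 with an estimated correlation). Fibrosis and stellate cell genes fell in 10 of 31 cases and rose in 1, with a median of -0.38 (adjusted p = 0.00043, adjusted p = 0.28 with an estimated correlation). Macrophage markers fell in 6 of 30 cases and rose in 3 (adjusted p = 0.0025, adjusted p = 0.49 with an estimated correlation), T and NK cell markers fell in 2 of 25 (adjusted p = 0.0036, adjusted p = 0.43 with an estimated correlation) and neutrophil markers in 5 of 18 (adjusted p = 5.3e-05, adjusted p = 0.32 with an estimated correlation). The T and NK cell call was lost without wild type replicate 4 (adjusted p = 0.11; range 3e-06 to 0.43), with array weights and by fry (0.25), which also did not call macrophage (0.3) and neutrophil markers (0.094). Medians changed sign between slides for fibrosis genes (-0.53 to 0.19), macrophage (-0.93 to 0.28), T and NK cell (-0.64 to 0.33) and neutrophil markers (-2.97 to 0.13). Over the alternatives the medians ranged from -0.487 to -0.031 for T and NK cell markers and from -2.378 to -0.92 for neutrophil markers. Within macrophage markers Itgax, an integrin gene of inflammatory macrophages, fell by 3.13 ± 0.54, while Cd163, a scavenger receptor gene of resident macrophages, was at least 3.4-fold higher (adjusted p = 0.0045). Such a lower bound is given where 0 of 4 arrays of a group were well above background, and it sets the other group's mean, array by array, against the higher of the lowest signal among probes well above background and the dim probe's own signal. Endothelial markers fell in 3 of 25 cases (adjusted p = 5.3e-05, adjusted p = 0.3 with an estimated correlation), with Lyve1 lower by a log2 change of -2.91 ± 0.27. Erythroid markers fell in 3 of 12 cases and rose in 2 (adjusted p = 0.024, adjusted p = 0.46 with an estimated correlation), a call lost without wild type replicate 3 (0.18) or E2f1 knockout replicate 3 (0.066) and by fry (0.25), over a range of 0.00049 to 0.46. Markers of B cells (1 of 14 higher), cholangiocytes (1 of 14 higher, 3 lower), adipocytes (0 of 7), exocrine pancreas (1 of 7 higher, 1 lower) and skeletal muscle (1 of 5 higher) were not called (adjusted p 0.53, 0.55, 0.55, 0.95 and 0.14). Fry called the skeletal muscle list higher (0.011, range 0.011 to 0.72).

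Male-biased liver genes rose in 18 of 22 cases and fell in 0 (19 and 0 adjusted over the list alone), with a median of 2.06 and 0.94 to 2.50 within slides (adjusted p = 3.2e-09, adjusted p = 0.29 with an estimated correlation). Cyp4a12a, a male-biased cytochrome gene, rose by 3.44 ± 0.82. Female-biased genes fell in 8 of 21 cases and rose in 0 (9 and 0 adjusted over the list alone), with a median of -0.96 (adjusted p = 1.3e-05, adjusted p = 0.3 with an estimated correlation). Over 26 alternatives that median ranged from -1.101 to -0.363 and the adjusted p from 1.1e-07 to 0.3, and the call was also lost with probes above background on all 12 arrays. The Y-linked gene Eif2s3y was well above background on all 12 arrays and rose by 0.59 ± 0.15, while the sex chromosome list as a whole was not called (1 of 4 higher, adjusted p = 0.55). Clock genes rose in 11 of 18 cases and fell in 1 (12 and 2 adjusted over the list alone), with a median of 1.46 (adjusted p = 0.00015, adjusted p = 0.28 with an estimated correlation). Dbp, an output gene of the clock, rose by 2.92 ± 0.52, whereas Arntl, of its activating arm, fell by 2.30 ± 0.55 and was above background on 3 of 4 E2f1 knockout arrays. Immediate early genes fell in 5 of 21 cases (adjusted p = 0.00015, adjusted p = 0.2 with an estimated correlation). Housekeeping genes rose in 2 and fell in 2 of 20 cases (adjusted p = 0.55), and their list was called lower with quantile normalization and with the series matrix values, over a range of adjusted p of 0.018 to 0.87. For the lists of cholesterol synthesis, lipoproteins, NRF2 targets, acute phase, cholangiocytes, exocrine pancreas, sex chromosomes and housekeeping genes, the median, its distance from the median of all genes, the mean and the camera direction did not share a sign.

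The largest changes included genes that were above background on 0 of 4 wild type arrays. AA414992 was at least 67.0-fold and Rbbp9 at least 22.3-fold higher in E2f1 knockout livers (adjusted p = 2.79e-08 and 7.35e-10). Nuggc and the interferon-inducible gene Ifi202b were at least 21.5-fold and 17.6-fold higher (adjusted p = 1.78e-05 and 6.17e-07). A second Rbbp9 probe, above background on all arrays, changed by -0.48. Differences of strain, or of the sequence under a probe, were not tested as a source of the largest single-gene changes, here or in the later comparisons. Gdpd3, encoding a lysophospholipase D, fell by 6.70 ± 0.40 (adjusted p = 1.72e-06) and was well above background on 2 of 4 knockout arrays.

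**Figure D2:**
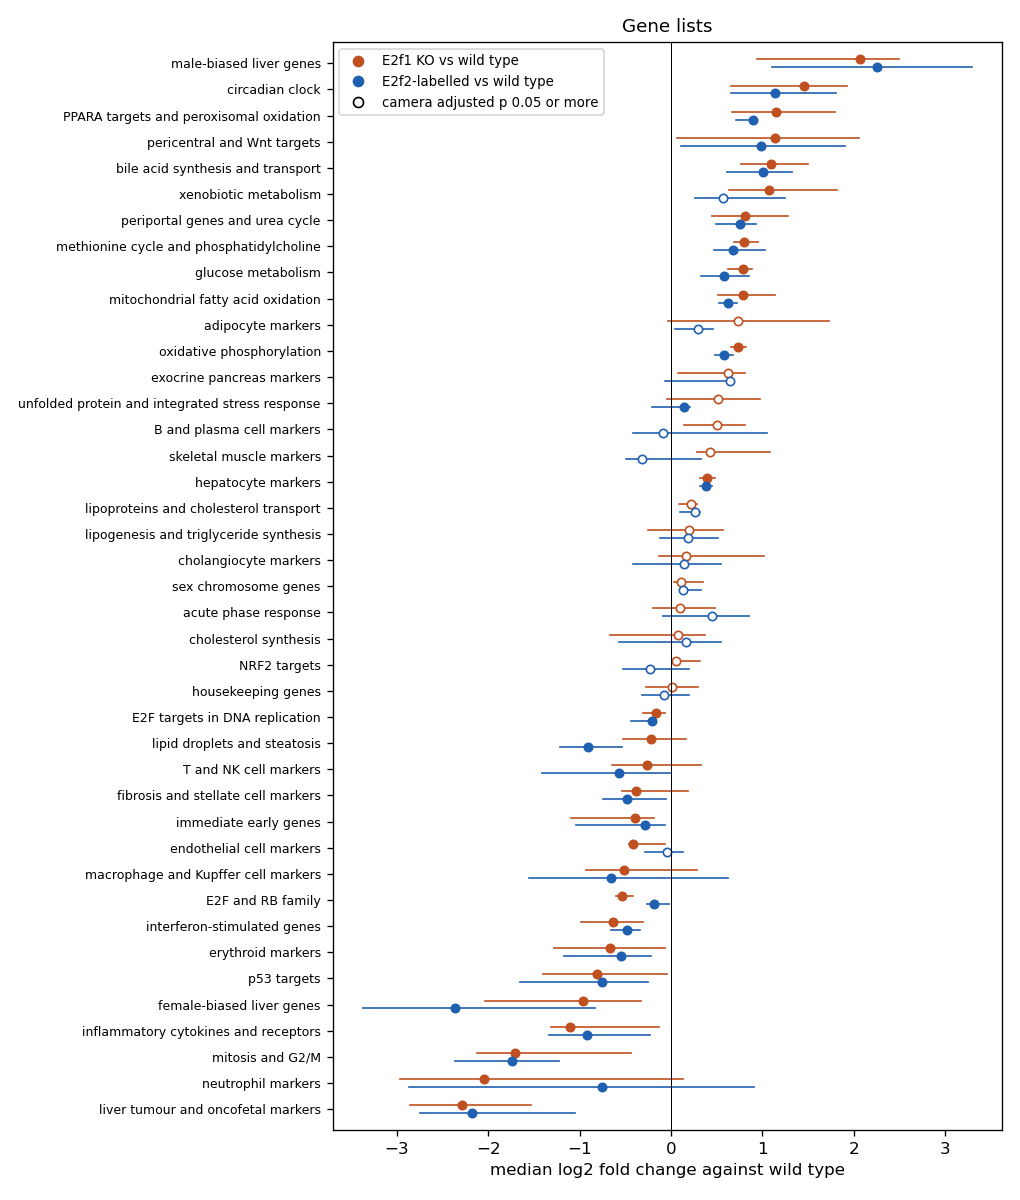
Points are the median log2 fold change of each gene list against wild type and lines span the lowest and highest of the 4 slides, with open points for lists that camera with a preset correlation did not call. Male-biased genes had the highest median in both groups (2.06 and 2.25), and the lowest was that of liver tumour markers in E2f1 knockout (-2.29) and of female-biased genes in E2f2-labelled livers (-2.36).

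The comparison of E2f2-labelled with wild type livers asks the same of E2F2. Camera called 27 of 41 lists with a preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.15). By the preset test, cell division, tumour, inflammatory and female-biased genes were lower, and oxidation, respiration, male-biased and clock genes higher. Lipid droplet genes and markers of T and NK cells were lower here as well.

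Limma called 4565 of 20576 genes, with 3006 higher and 1559 lower (65.8% higher), and 2155 differed at least 2-fold (1044 higher, 1111 lower). The median of all genes lay at 0.18 and, with quantile normalization, at 0.07, where 49.5% of 3822 called genes were higher. Values did not overlap in 4900 genes, against 2.86% by chance. Without wild type replicate 2 the count was 2746, and with the slide as a block it was 6295, with 4492 genes in both fits.

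Mitosis genes fell in 24 of 31 cases and rose in 0 (25 and 0 adjusted over the list alone), with a median of -1.74 and -2.36 to -1.22 within slides (adjusted p = 6.9e-19, adjusted p = 0.15 with an estimated correlation). Over 26 alternatives the median ranged from -2.037 to -0.691, the smallest with normexp. Mki67 fell by 2.94 ± 0.54 (adjusted p = 0.00381) and the spindle protein gene Prc1 fell by 2.95 ± 0.48, with 2 of 4 E2f2-labelled arrays above background. Of the 41 replication targets, 8 fell and 2 rose (12 and 4 adjusted over the list alone; adjusted p = 0.00032, adjusted p = 0.17 with an estimated correlation; median -0.211, and -0.3 to -0.105 over alternatives), with Mcm6 lower by a log2 change of -1.65 ± 0.37. The E2F and RB family (7 of 24 lower, 1 higher) had a median of -0.19 (adjusted p = 0.0031, adjusted p = 0.15 with an estimated correlation). Targets of p53 fell in 12 of 25 cases and rose in 1 (adjusted p = 2.4e-08, adjusted p = 0.16 with an estimated correlation), with Cdkn1a lower by -3.02 ± 0.52. Tumour markers fell in 21 of 32 cases and rose in 0 (22 and 0 adjusted over the list alone), with a median of -2.18 and -2.75 to -1.05 within slides (adjusted p = 7.4e-17, adjusted p = 0.15 with an estimated correlation). Akr1c18 fell by 6.05 ± 0.66 (adjusted p = 0.000208), and Gpc3 fell by 5.35 ± 1.15, with 2 of 4 E2f2-labelled arrays above background.

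Oxidative phosphorylation genes rose in 24 of 35 cases and fell in 0 (31 and 0 adjusted over the list alone), with a median of 0.58 and 0.48 to 0.68 within slides (adjusted p = 1.2e-07, adjusted p = 0.4 with an estimated correlation). Fatty acid oxidation genes rose in 15 of 26 cases and fell in 0 (19 and 0 adjusted over the list alone), with a median of 0.63 (adjusted p = 1.8e-05, adjusted p = 0.4 with an estimated correlation). PPARA targets rose in 15 of 30 cases and fell in 1 (adjusted p = 0.01, adjusted p = 0.59 with an estimated correlation), and bile acid genes rose in 11 of 22 and fell in 2 (adjusted p = 0.026, adjusted p = 0.54 with an estimated correlation). Those calls were lost without wild type replicate 1 (adjusted p = 0.053, range 0.00038 to 0.59) and without E2f2-labelled replicate 3 (adjusted p = 0.063, range 0.0012 to 0.54), respectively. Lipid droplet genes fell in 9 of 25 cases and rose in 2 (12 and 4 adjusted over the list alone), with a median of -0.91 (adjusted p = 4e-05, adjusted p = 0.15 with an estimated correlation), and the fatty acid carrier gene Fabp4 fell by 3.50 ± 0.73. Lipogenic genes rose in 4 and fell in 4 of 26 cases (adjusted p = 0.65), with Scd2 lower by -4.28 ± 0.43 and Thrsp, a lipogenic regulator, higher by 2.07 ± 0.40. Cholesterol synthesis (5 of 26 higher, adjusted p = 0.78), lipoproteins (4 of 25 higher, 3 lower, adjusted p = 0.72) and xenobiotic metabolism (10 of 33 higher, 4 lower, adjusted p = 0.48) were not called.

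Glucose metabolism (9 of 26 higher, 2 lower), periportal (11 of 22 higher, 1 lower), pericentral (9 of 22 higher) and methionine cycle genes (14 of 24 higher, 2 lower) had medians of 0.58, 0.76, 0.99 and 0.68 (adjusted p 0.0074, 0.00095, 0.00032 and 0.0031; adjusted p = 0.54, 0.4, 0.54 and 0.54 with an estimated correlation). Pck1 rose by 2.16 ± 0.24 and the periportal gene Cyp2f2 by 2.33 ± 0.44. Hepatocyte markers rose in 8 of 28 cases, with a median of 0.39 (adjusted p = 0.019, adjusted p = 0.54 with an estimated correlation). Their call was lost without wild type replicate 1 (adjusted p = 0.089) and with normexp, and their test direction turned with quantile normalization (median 0.05, adjusted p = 0.937) and with the series matrix values (median 0.04, adjusted p = 0.9), over a range of 0.00071 to 0.94. The unfolded protein response was called lower (3 of 29 higher, 6 lower, adjusted p = 0.042, adjusted p = 0.54 with an estimated correlation) although its median was 0.14. That call was lost without wild type replicate 2 (0.12), E2f1 knockout replicate 1 (0.058), E2f1 knockout replicate 3 (0.055) or E2f2-labelled replicate 4 (0.07), with the slide as a block (0.084) and by fry (0.41), and held in 15 of 26 alternatives (range 0.0068 to 0.54). NRF2 targets (4 of 22 higher, 4 lower) and the acute phase response (5 of 30 higher) were not called (adjusted p = 0.084 for both). They passed without wild type replicate 2 (0.016 and 0.024) or E2f2-labelled replicate 3 (0.043 and 6.1e-05), and the acute phase response also without wild type replicate 4 (0.044). The iron hormone gene Hamp rose by 3.78 ± 0.81.

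Inflammatory cytokines and receptors fell in 12 of 28 cases and rose in 3 (adjusted p = 7.8e-08, adjusted p = 0.16 with an estimated correlation), and interferon-stimulated genes fell in 13 of 32 and rose in 1 (adjusted p = 9.4e-09, adjusted p = 0.16 with an estimated correlation). The median of the inflammatory list was -0.92, and -1.08 to -0.305 over the alternatives. The chemokine gene Cxcl9 fell by 2.50 ± 0.25 and Ifi44 by 2.14 ± 0.29. Fibrosis genes fell in 10 of 31 cases (adjusted p = 1.4e-06, adjusted p = 0.15 with an estimated correlation), with Col1a1 lower by -2.24 ± 0.47 and Col4a1 by -1.90 ± 0.27. Macrophage markers fell in 11 of 30 cases and rose in 2 (adjusted p = 6.9e-06, adjusted p = 0.4 with an estimated correlation), T and NK cell markers fell in 9 of 25 (adjusted p = 1.3e-06, adjusted p = 0.26 with an estimated correlation) and neutrophil markers in 4 of 18 (adjusted p = 0.0024, adjusted p = 0.54 with an estimated correlation). By fry neither macrophage (0.073) nor neutrophil markers (0.32) passed. Neutrophil medians within slides spanned -2.87 to 0.91 and macrophage medians -1.55 to 0.63. Over the alternatives the medians ranged from -1.496 to -0.138 for neutrophil markers and from -0.798 to -0.221 for T and NK cell markers. Cd163 was at least 3.1-fold higher (adjusted p = 0.00509), and Itgax fell by 4.25 ± 0.54. Erythroid markers fell in 3 and rose in 2 of 12 cases (adjusted p = 0.044, adjusted p = 0.54 with an estimated correlation). That call was lost with the slide as a block (0.054) and without wild type replicate 2 (0.082) or 3 (0.23) or E2f2-labelled replicate 1 (0.13), 2 (0.063) or 4 (0.07) and by fry (0.41), and held in 15 of 26 alternatives (range 0.0015 to 0.54). Not called were markers of endothelium (3 of 25 higher, 4 lower, adjusted p = 0.079), B cells (0 of 14, 0.32), cholangiocytes (3 of 14 lower, 0.19), adipocytes (1 of 7 higher, 1 lower, 0.92), exocrine pancreas (1 of 7 higher, 1 lower, 0.92) and skeletal muscle (1 of 5 higher, 0.78). The endothelial list was called lower without E2f2-labelled replicate 3 (0.013) and the B cell list without wild type replicate 1 (0.041).

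Male-biased genes rose in 18 of 22 cases and fell in 0 (21 and 0 adjusted over the list alone), with a median of 2.25 and 1.11 to 3.29 within slides (adjusted p = 5.4e-10, adjusted p = 0.25 with an estimated correlation). Female-biased genes fell in 13 of 21 cases and rose in 0 (15 and 0 adjusted over the list alone), with a median of -2.36 (adjusted p = 3.9e-12, adjusted p = 0.15 with an estimated correlation). Cyp4a12a rose by 4.90 ± 0.82 (adjusted p = 0.00254), and the female-biased cytochrome gene Cyp2b13 was at least 45.7-fold lower (adjusted p = 0.000102). Sex chromosome genes were not called (1 of 4 higher, adjusted p = 0.48), with Eif2s3y higher by 0.63 ± 0.15. Clock genes rose in 11 of 18 cases and fell in 2 (12 and 2 adjusted over the list alone), with a median of 1.14 (adjusted p = 0.00037, adjusted p = 0.26 with an estimated correlation). Dbp rose by 2.70 ± 0.52 and Arntl fell by 2.88 ± 0.55, above background on 3 of 4 E2f2-labelled arrays. Immediate early genes fell in 7 of 21 cases (adjusted p = 0.00037, adjusted p = 0.15 with an estimated correlation), with a median between -0.477 and -0.062 over the alternatives. Housekeeping genes (1 of 20 higher, 3 lower) were not called (adjusted p = 0.079), but were called lower with quantile normalization and with the series matrix values and without wild type replicate 4 (0.044) or E2f2-labelled replicate 3 (0.047), over a range of 0.0014 to 0.54. Median, distance from all genes, mean and camera direction did not share a sign for lipogenesis, cholesterol synthesis, lipoproteins, the unfolded protein response, B cells, cholangiocytes, adipocytes, exocrine pancreas, skeletal muscle and sex chromosomes. Among single genes, Trim12a was at least 61.1-fold lower (adjusted p = 3.03e-10), and Esm1, an endothelial proteoglycan gene, fell by 6.21 ± 0.53 (adjusted p = 2.91e-05).

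**Figure D3:**
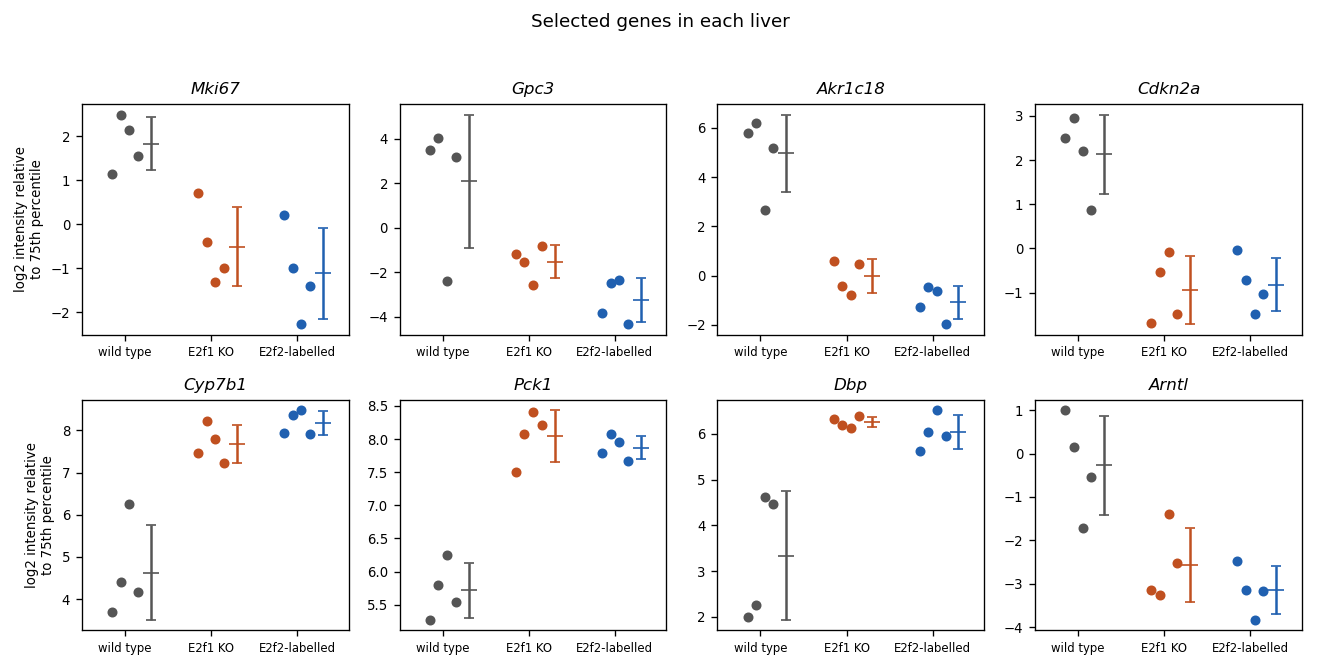
Points are single livers, and bars with whiskers are the mean and SD (n = 4) of 8 genes as log2 intensity relative to the array's 75th percentile. Mki67, Gpc3, Akr1c18, Cdkn2a and Arntl averaged lower in E2f1 knockout and E2f2-labelled livers and Cyp7b1, Pck1 and Dbp higher, and the Gpc3 value of wild type replicate 3 was -2.40.

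Both contrasts use the same wild type arrays, which by itself makes their fold changes alike. Genes called in both numbered 2776 in the same direction (1774 higher, 1002 lower) and 15 in opposite directions. Simulated unchanged groups, compared with a shared set of simulated wild type arrays, had 0.02 such genes on average over 100 simulations. All simulated arrays held independent noise for each gene at its estimated spread. They leave out correlation between genes and slide effects, so their shared count is low by design. Independent lists of the real sizes would share 511.3 genes (395.8 higher, 115.5 lower). Across genes, which are not independent replicates, the fold changes correlated with r of 0.818 against 0.502 in the simulations, and 82.1% against 66.7% had the same sign. The covariance was 0.502 against 0.043, a difference of 0.459. With wild type replicates 1 and 2 set against one of these groups and 3 and 4 against the other, 944 and 1015 genes were shared and r was 0.591 and 0.616. The shared count fell to 1492 without wild type replicate 2. Among genes with the largest smaller change of the pair were AA414992, at least 45.3-fold higher in E2f2-labelled livers, and Gdpd3, lower there by -6.67 ± 0.40 and well above background on 2 of 4 arrays. Klrb1b, a natural killer cell receptor gene, was also among them, at least 29.0-fold lower in E2f2-labelled livers (adjusted p = 4.35e-06). It was also lower in E2f1 knockout livers (adjusted p = 4.85e-05), by an uncertain amount because 1 of 4 arrays was above background.

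**Figure D4:**
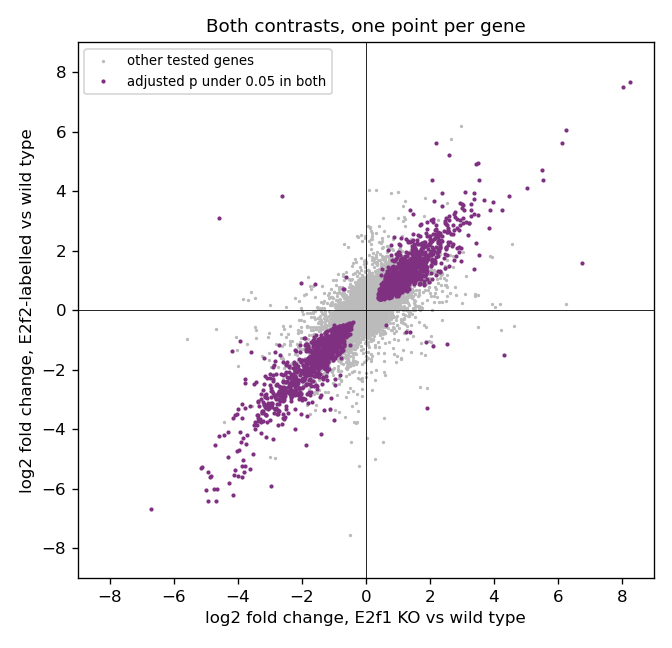
Each point is 1 of the tested genes, with its log2 fold change against wild type in E2f1 knockout (horizontal) and E2f2-labelled livers (vertical). The 2776 genes called in both with the same sign lie along the diagonal (r = 0.818 across genes), with 15 called in opposite directions.

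The comparison of E2f2-labelled with E2f1 knockout livers asks whether the groups differ from each other. They differed in fewer genes than either did from wild type, and at most 3 members of any list passed in either direction. No tested gene of mitosis, DNA replication or the p53 targets passed.

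Limma called 337 of 20576 genes, with 188 higher and 149 lower in E2f2-labelled livers (55.8% higher), and 259 differed at least 2-fold (136 higher, 123 lower). The median of all genes lay at 0.03. At an unadjusted p under 0.05 there were 2363 genes, and values did not overlap in 1855, against 2.86% by chance. With the slide as a block 436 genes passed, 299 of them in both fits. In the lists of mitosis, replication targets and p53 targets, 0 of 31, 41 and 25 members passed (camera adjusted p = 0.22, 0.11 and 0.73; adjusted p = 0.86, 0.71 and 0.98 with an estimated correlation). The mitosis list was called lower without E2f1 knockout replicate 3 (0.008, range 0.008 to 0.86). Replication targets were called lower without E2f1 knockout replicate 3 (0.022) or 4 (0.021) or E2f2-labelled replicate 1 (0.026), over a range of 0.021 to 0.71. E2f2 itself was higher than in E2f1 knockout livers by 1.24 ± 0.21 (adjusted p = 0.00955), and was the 1 member of its family that passed, whereas E2f1 (0.66 ± 0.19, adjusted p = 0.133) and Cpt2 (0.02 ± 0.24, adjusted p = 0.992) did not.

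Camera with a preset correlation called 16 lists, 14 lower and 2 higher. Camera with an estimated correlation called 0 (smallest adjusted p = 0.65), as did fry, so no list shift is claimed between these groups. The medians of those 14 lists lay between -1.17 for female-biased genes (3 of 21 fell, adjusted p = 2.8e-06, adjusted p = 0.71 with an estimated correlation) and -0.06 for fibrosis genes. Among members that passed, Lpin2, of triglyceride synthesis, was lower by -1.51 ± 0.27 (adjusted p = 0.0128) and the carboxylesterase gene Ces1g by -3.73 ± 0.56 (adjusted p = 0.00402). Cxcl9 was lower by -1.53 ± 0.25 (adjusted p = 0.00577). The endothelial gene Dnase1l3 was higher by 1.62 ± 0.26 (adjusted p = 0.0052) and the male-biased gene Cspg5 by 2.57 ± 0.34 (adjusted p = 0.00174).

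Among single genes, Ifi202b was at least 17.6-fold lower (adjusted p = 1.33e-06) and Trim12a at least 43.0-fold lower (adjusted p = 7e-10). Dct was higher (adjusted p = 0.000157), by an amount that is uncertain because it was well above background on 1 of 4 E2f1 knockout arrays. Enpp1 was at least 10.5-fold lower on its brighter probe (adjusted p = 3.02e-07), while its second probe differed by -0.21. On chromosome 4, which carries E2f2, the zinc finger gene Zfp982 (mm9 start 146887459) was at least 16.5-fold lower and the ubiquitin ligase gene Fbxo44 (mm9 start 147527012) at least 7.41-fold lower (adjusted p = 9.1e-05 and 2.42e-05).

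**Figure D5:**
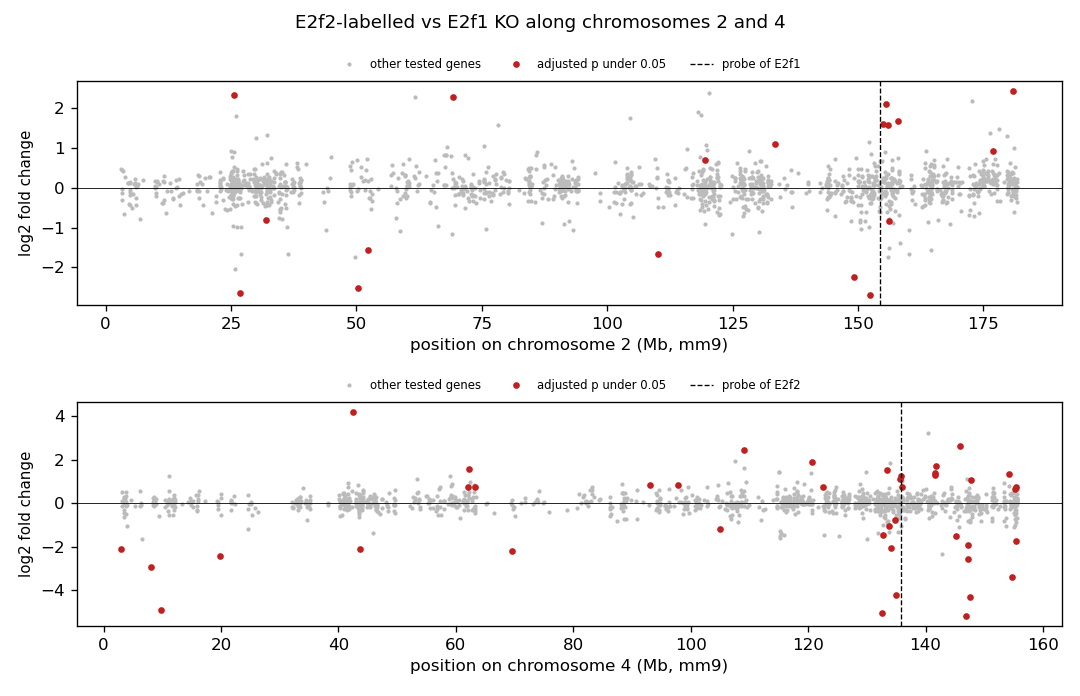
Points are tested genes by mm9 position along chromosomes 2 and 4 (Mb) and their log2 fold change between E2f2-labelled and E2f1 knockout livers, with called genes in red and the E2f1 and E2f2 probes as dashed lines. Within 20 Mb of either probe 34 of 1071 genes were called (3.17%), against 290 of 19247 elsewhere (1.51%).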

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

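In 13 of 294 groups of a named gene (4.4%) and 7 of 123 group medians of a list (5.7%), 1 liver lay far from the other 3, where chance gives about 1 in 20. In wild type livers these were Gpc3 in replicate 3 (-2.40, others 3.17 to 4.05), Cdkn3 in replicate 2 (-0.77, others -1.74 to -1.64), Lpl in replicate 3 (2.99, others 4.27 to 4.51) and Slco1a1 in replicate 3 (2.96, others -0.37 to 0.16). In E2f1 knockout livers they were Uhrf1 (-1.16, others -2.11 to -1.97), Psrc1 (-3.81, others -4.92 to -4.79) and Ltf (0.44, others -3.93 to -3.89) in replicate 1 and Lyve1 (-1.29, others -2.21 to -2.19) and Hamp (3.12, others 5.64 to 6.13) in replicate 2. Replicate 3 stood apart for Cyp2b13 (-4.35, others -2.41 to -2.32). In E2f2-labelled livers they were Ccl4 in replicate 2 (-1.49, others -2.50 to -2.38) and, in replicate 1, Hsd3b5 (5.71, others 6.28 to 6.38) and Slc22a27 (-6.13, others -5.75 to -5.72). Among list medians they were p53 targets in E2f2-labelled replicate 1 (0.43, others -0.04 to 0), lipid droplets (2.15, others 0.98 to 1.10) and adipocyte markers (2.53, others -2.44 to -2.28) in E2f1 knockout replicate 1, and erythroid markers in E2f2-labelled replicate 3 (4.58, others 3.24 to 3.32). In wild type they were lipoproteins in replicate 4 (4.73, others 3.96 to 4.05) and cholangiocyte markers (-1.76, others -0.82 to -0.65) and housekeeping genes (6.02, others 6.41 to 6.43) in replicate 3. Wild type replicate 3 and E2f1 knockout replicate 1 each held 3 of the genes and 2 of the list medians.

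The 2 tests of where the differing genes lie were chosen only after the result was seen. Genes called between E2f1 knockout and E2f2-labelled livers were 2.11 times as frequent within 20 Mb of the targeted genes as elsewhere (Fisher's exact p = 0.00013). In a permutation of window positions, random pairs gave a ratio as high with p = 0.065 (10000 pairs), so strain DNA carried along with the targeted alleles and chance clustering cannot be told apart. Of 34 nearby called genes 73.5% deviated more from wild type in the knockout labelled as their own (exact binomial p = 0.009, although neighbouring genes are not independent). These were 5 of 7 genes near E2f1 and 20 of 27 near E2f2, so most of the nearby called genes ran with the labels. The E2f1 probe did so too (-0.82 in E2f1 knockout and -0.16 in E2f2-labelled livers). The E2f2 probe ran against the labels (-1.50 and -0.26). Because these values go both ways, exchanged labels cannot be told apart from correct ones. Comparison of the probe positions with the deleted exons would show whether these probes can check the labels at all.

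The 3 tests of why E2f1 knockout and E2f2-labelled livers shift the same genes were chosen only after the result was seen. With no wild type array shared, the lower of the 2 correlations was 0.591, so chance values shared through the wild type arrays did not account for the overlap. Wild type pieces that differ in tumour content remain a candidate explanation: the median absolute r of differences between wild type livers with the knockout effect was 0.318 over 6 pairs (0.106 to 0.533), against 0.143 over 12 knockout pairs (0.032 to 0.278). That test is not specific to tumour content. For the conflicting diet label, lipid droplet genes differed by -0.484 between E2f2-labelled and E2f1 knockout livers (fry adjusted p = 0.26). E2f1 knockout replicate 1 stood apart on that list (2.15), and the difference was no smaller without it. Chow in the E2f1 knockout mice would predict lipid droplet genes to be higher in E2f2-labelled livers. The difference ran the other way but did not pass by fry, so chow and high-fat diet cannot be told apart. Vehicle in place of diethylnitrosamine was not tested. A difference of strain between the wild type mice and both other groups was not tested.

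The 2 tests of the clock genes were chosen only after the result was seen. Genes that peak in the light phase and those of the opposite phase differed in their median shift by 2.06 in E2f1 knockout livers (1.89 and -0.17) and by 2.37 in E2f2-labelled livers (2.27 and -0.10), over 11 and 5 genes. A different time of killing is a candidate explanation that would give this pattern of 2.06, and an effect of genotype on the clock would too. Scaling did not account for it, since 9 of the 11 clock genes called in both comparisons stayed called under quantile normalization.

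Counts over regrouped arrays were chosen before the result was seen. Among 35 splits of the 8 arrays, a count of called genes as large as the real one occurred in 1 split, the real one, for E2f1 knockout (4234, highest other 5), E2f2-labelled (4565, highest other 3) and the direct comparison (337, highest other 2). Those splits ignore the slides, whose arrays had correlated deviations, so they do not by themselves exclude chance. The 8 splits that exchange arrays only within slides are too few for a share under 0.05, and each of the others among them called 0 genes. The number of called lists was as large in 1 of 35 splits for E2f1 knockout (28, highest other 25) and 1 of 35 for E2f2-labelled livers (27, highest other 24). In the direct comparison 6 of 35 splits gave as many lists as the 16 found (highest other 18), so chance was not excluded there. Camera with a preset correlation thus called many lists in regrouped arrays. Splits that exchange 1 or 3 arrays keep part of the real difference, so not all of their calls are false. The splits that exchange 2 arrays are balanced and called 6 to 20 lists for E2f1 knockout. The shared count of 2776 was reached in 1 of 100 regroupings, the real one (highest other 0). Those regroupings mix wild type arrays with the others, which widens the spread within groups and makes a low count likely. They do not test whether the sharing between E2f1 knockout and E2f2-labelled livers exceeds chance.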

How the results depend on the processing

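With a correlation estimated per list, camera called 0, 0 and 0 lists in the E2f1 knockout, E2f2-labelled and direct comparisons, against 28, 27 and 16 with the preset one (smallest adjusted p 0.18, 0.15 and 0.65), and fry called 0 in the direct comparison and ended 6 calls and added 1 for E2f1 knockout and ended 4 for E2f2-labelled livers. That comparison gave 337 genes, 217 with normexp, 208 with probes above background on all 12 arrays and 519 with array weights. Without a filter on dim probes the counts were 2789 for E2f1 knockout, 2989 for E2f2-labelled livers and 1655 shared. Leaving out single arrays gave 2511 (without wild type replicate 2) to 4898 (without 3) for E2f1 knockout, 2746 to 5272 for E2f2-labelled livers and 1492 to 3529 shared, without the same replicates. With the slide as a block the counts were 5487, 6295 and 436. Separate wild type arrays for each knockout gave 944 and 1015 shared genes and r of 0.591 and 0.616, against 2776 and 0.818. The median of hepatocyte markers in E2f2-labelled livers fell from 0.39 to 0.046 with quantile normalization and 0.043 with series matrix values, and the direction of the test turned. Rbbp9 changed by -0.484 and -0.846 with probes above background on all 12 arrays, where its other probe is used. Amy2a5 in E2f2-labelled livers changed by -0.015 with the mean of all probes, which includes a second probe that was lower. Mcm3 in E2f1 knockout livers changed by -0.98, by -1.129 without E2f1 knockout replicate 1 and by 0.041 without E2f2-labelled replicate 3 or 4, where another probe is used. The cause of the other differences was not tested.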
